A study of Homo sapiens with 414 samples.

How the data were processed

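Per the labels, cells were seeded and given a compound on the same day, lysed on the plate after 1 to 39 days, and RNA was taken up with a 96-well silica kit and made into TruSeq RNA libraries. Per the submitters' processing notes, the tools were CASAVA 1.8.2, Bowtie 0.12.8 and RSEM 1.2.1 and the genome build was hg19. The values analysed are the gene-level TPM the authors deposited, 1 column per library. Column sums lay between 999999.07 and 1000001.05, which fits TPM. There were 19084 gene symbols, of which 18925 were above 0 in some library and 159 were listed at 0 throughout. Read counts were not analysed here, so no count model was fitted, the reads behind a TPM are unknown, and a listed 0 is not proof of absence.

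Groups, days and doses were taken from the labels. Genes with at least 1 TPM in at least 5 libraries were tested, 16318 in all. Differences were fitted with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8) on log2(TPM + 1) with an intensity trend, and Benjamini-Hochberg adjusted p-values under 0.05 were called. The time comparisons came from 1 fit to the 148 non-toxic libraries with day as a factor. The class comparisons used 1 value per compound, the mean over days of its deviation from the non-toxic mean of that day, for compounds with at least 3 libraries in the window. Because limma's variance trend then runs on mean deviations, the class fits were repeated with the trend on the mean log2 expression of a gene, an alternative added after the results were seen. Each compound was fitted against the non-toxic libraries of its own days with day as a factor and compound as a random block, whose correlation was 0.0212. Pairs of compounds were fitted on shared days with day as a factor. DMSO entered as 1 of the non-toxic compounds, because it had no library of its own for each compound and its vehicle role is not stated.

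Genes are named from those that meet a rule written with the design, and not every such gene is named. For each time comparison these are the 10 largest rises and falls by log2 difference among called genes with at least 5 TPM on either day, for each class or pair comparison the 5 largest each way. For each compound they are the 3 largest each way among called genes with at least 1 TPM in either group and the same sign on at least 80% of its days, with the members of the list matched to it. Examples from any other list are taken from its members with the largest differences.

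Of 37 gene lists written down in advance, 36 were tested. The mitochondrially encoded list had 0 of 8 genes measured, the cholesterol list 16 of 17 and the microglia list 3 of 9. Lists were tested with cameraPR on the moderated t-values, once with a preset correlation of 0.01 between genes and once with an estimated one. The estimate came from the residuals of the non-toxic libraries. Each was adjusted within its family of comparisons. Shared calls of 3 pairs of compounds were compared with those of 20 simulations in which no compound had an effect, whose highest count was 0. Compounds without an effect leave few calls to share, so this count says little. The 16 non-toxic compounds were also divided at random into 8 and 8 so that the compounds of a pair had no control in common. Neither covers technical features that toxic libraries may share, and the overlaps were not counted again without libraries of a strong length trend.

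The length trend of a library is the slope of its deviation from the same-day non-toxic mean on log2 transcript length, over genes with a mean of at least 10 TPM. Lengths were taken from GENCODE 29, where 9611 of 10328 such genes (93.1%) matched by symbol. Its limits of -0.15 and -0.1, its use as a covariate and the exclusion of days 15 and 21, of the retinoids from the class comparisons and of the day 8 ibuprofen library were chosen after the data had been seen. The fits were tested on simulated data with 200 planted genes. A planted log2 difference of 1 was recovered in 98.5% to 100% of genes, except 85.1% for AraC against 5-fluorouracil, where a difference of 0.5 was recovered in 47.8%. Differences of 0.2 were recovered in 95.5% and 94% of genes for the class comparisons, and 0 to 19 unplanted genes were called. There the toxic compounds had only the spread of non-toxic libraries and shared the same planted difference. Recovery among real toxic compounds, which also differ from each other, was not measured and can be lower. The libraries drawn for these simulations left out ibuprofen, and those for the overlaps left out its day 8 library. As a check of identity, no 2 libraries were the same, and the closest, L-phenylalanine and permethrin on day 3, correlated at 0.9958.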

Results

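The series screened compounds for neurotoxicity on H1-NPC cultures, which are neural progenitor cells derived from the human embryonic stem cell line H1. RNA was sequenced from 266 libraries of 29 compounds labelled toxic and 148 of 16 compounds labelled non-toxic, DMSO at 0.1% among them. Every compound was given from the day of seeding, at 1 dose, and sampled once or not at all on each of 11 days, from day 1 to day 39. The non-toxic class had 7 to 16 libraries per day and the toxic class 19 to 29. Arsenic, busulfan, cadmium, cytosine beta-D-arabinofuranoside (AraC), okadaic acid and vincristine had 5 libraries each, from days 1 to 6, and aspirin 5 as well. The replicates of a compound were therefore single wells of different days, and how independent those wells were is not stated. Expression was analysed as TPM, each transcript's share of a library, without read counts, so the depth of each library is unknown. Between 11377 and 17188 genes reached 1 TPM in a library, the upper value in vincristine on day 4.

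Differences below are on the log2 scale of TPM plus 1, printed ± SE, and TPM are printed ± SD over the libraries of a group. For a compound the SD runs over its days, beside the day means of the non-toxic class, and for the classes over the means of the compounds. A gene rose or fell where the adjusted limma p was under 0.05. For each gene list, fixed before the data were examined, the members that passed among all 16318 tested genes are counted, then those that passed adjusted over the list alone. List p-values are adjusted cameraPR values, taken with an estimated correlation between genes. Of 1008 list tests on compounds, 289 passed with a preset correlation and 94 of those also with the estimated one. The corresponding numbers were 23 and 9 of 72 tests for time, 26 and 3 of 72 for class, and 39 and 9 of 180 for pairs of compounds. Lists called changed below held under both unless a p above the threshold is printed. The correlation estimated in the non-toxic libraries was 0.0067 for HOX genes and 0.0101 for metallothioneins and zinc export, beside the preset 0.01. For these lists the second test is hardly stricter than the first, and correlation among induced members is not covered.

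How the cultures developed without a toxic compound was read from the non-toxic libraries, first between day 1 (16 libraries) and day 10 (15 libraries). Synaptic genes rose as a group, 12 of 12 measured (12 adjusted over the list alone; list p = 5.19e-05). Among them SYN1, a protein of synaptic vesicles, rose by 3.03 ± 0.06. Genes of the inhibitory transmitter GABA followed the same direction: GAD2, which makes GABA, went from 1.59 ± 0.502 to 99.2 ± 8.60 TPM, and the vesicular transporter SLC32A1 rose by 5.61 ± 0.09. In that list 4 of 7 measured genes rose, 1 fell and 2 did not pass (4 and 1 adjusted over the list alone; list p = 3.33e-05). The largest single rises were PCP4, a calmodulin-binding protein, by 8.64 ± 0.14 (691 ± 42.4 against 0.869 ± 0.796 TPM), the nuclear receptor ESRRB by 6.31 ± 0.07, CA8 by 6.05 ± 0.10, CNTNAP4 by 6.00 ± 0.09 and LRRC3B by 5.78 ± 0.10.

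Dividing-cell genes moved the other way by day 10. All 14 S phase genes fell (14 adjusted over the list alone; list p = 3.33e-05), MCM2 with -2.48 ± 0.04 and CDC6 with -2.40 ± 0.07. All 14 G2 and mitosis genes fell as well (14 adjusted over the list alone; list p = 0.0124), TOP2A from 363 ± 6.36 to 57.6 ± 6.71 TPM. The largest falls included the cartilage collagen COL2A1 with -3.90 ± 0.10, A2M with -3.86 ± 0.13, the vesicular glutamate transporter SLC17A8 with -3.67 ± 0.09, the chemokine CXCL12 with -3.59 ± 0.14 and HMGA2 with -3.39 ± 0.08. Of 14 pan-neuronal genes 12 rose and 2 fell (12 and 2 adjusted over the list alone), a list call with adjusted p = 0.201 with an estimated correlation. In total 5806 genes rose and 6588 fell, or 6526 and 6070 after centring each library on its median. With compound as a block the calls were as many within the limit of 1.5 times, and all 40 genes named for the time comparisons kept direction and call.

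Between day 10 and day 39 (14 libraries) the cultures gained glial transcripts. All 11 astrocyte genes rose (11 adjusted over the list alone; list p = 2.08e-05). The intermediate filament GFAP went from 43.9 ± 10.6 to 3530 ± 444 TPM, a difference of 6.32 ± 0.10, and the water channel AQP4 from 1.58 ± 0.356 to 284 ± 43.4 TPM. All 12 hypoxia and glycolysis genes rose too (12 adjusted over the list alone; list p = 2.08e-05), with carbonic anhydrase CA9 at 5.13 ± 0.12, VEGFA at 4.93 ± 0.12 and EGLN3 at 4.81 ± 0.12. Of 21 p53 targets 18 rose and 2 fell (18 and 2 adjusted over the list alone; list p = 0.00217), led by the cell cycle inhibitor CDKN1A with 4.35 ± 0.07. Of 13 ATF4 and amino acid response genes 12 rose and 1 fell (12 and 1 adjusted over the list alone; list p = 0.000366), NUPR1 by 4.36 ± 0.17 and STC2 by 4.32 ± 0.11.

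Neurogenic transcription factors fell over the same interval, 11 of 13 with 1 rise (11 and 1 adjusted over the list alone; list p = 0.0124): INSM1 with -3.32 ± 0.07 and the NOTCH pathway gene DLL3 with -2.22 ± 0.05. The largest falls of any gene included the neuropeptide gene TAC3 (-4.68 ± 0.12), OLIG3 (-4.37 ± 0.08) and the axon guidance receptor ROBO3 (-4.26 ± 0.08). The de novo DNA methyltransferase DNMT3B went to 5.65 ± 0.990 against 65.7 ± 6.03 TPM. Large rises outside the lists were the myelin lipid-binding protein PMP2 (6.90 ± 0.08), the prostaglandin D synthase PTGDS (6.45 ± 0.15), the lactate transporter SLC16A3 (6.10 ± 0.17) and ITPR1 (5.22 ± 0.06). All 12 mesenchymal and matrix genes rose (12 adjusted over the list alone), but the list had adjusted p = 0.135 with an estimated correlation. All 14 G2 and mitosis genes fell (14 adjusted over the list alone), with adjusted p = 0.125 with an estimated correlation. In total 7115 genes rose and 5696 fell.

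**Figure D1:**
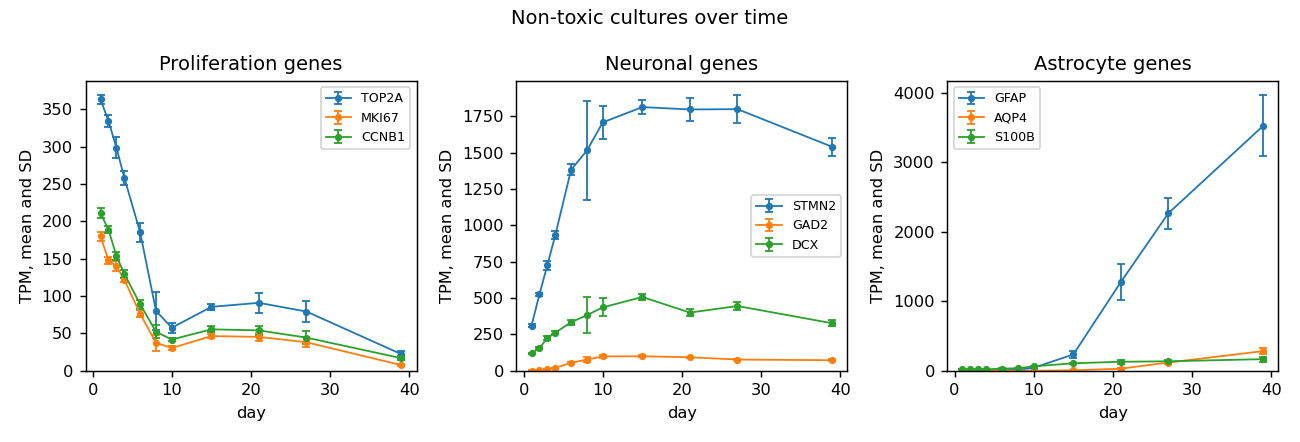
Mean TPM with SD of the non-toxic libraries on each of 11 days for genes of division (TOP2A, MKI67, CCNB1), neurons (STMN2, GAD2, DCX) and glia (GFAP, AQP4, S100B). TOP2A starts at 363 TPM on day 1, STMN2 reaches 1709 TPM on day 10, and GFAP is at 3530 TPM on day 39.

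What separated the compounds labelled toxic from those labelled non-toxic, the question of the series, was asked with 1 value per compound. Over days 1 to 6 (28 toxic against 16 non-toxic compounds) few genes differed. ATP5E of the ATP synthase was higher in the toxic class by 0.25 ± 0.05 (991 ± 185 against 809.5 ± 25.9 TPM) and UQCRQ of complex III by 0.17 ± 0.04. CDR1 rose by 0.52 ± 0.11 and the RNA exosome subunit EXOSC6 by 0.27 ± 0.06. The lysosomal membrane protein TMEM106B fell, with -0.44 ± 0.10, as did HCRT, the precursor of the neuropeptide orexin, with -0.49 ± 0.11. No single p53 target passed (0 adjusted over the list alone), yet the 21 genes as a list ranked above the rest (median 0.42; list p = 0.029). The stress cytokine GDF15 averaged 36.8 ± 105 against 0.815 ± 0.296 TPM and the cell cycle inhibitor CDKN1A 196 ± 362 against 22.5 ± 2.11 TPM. HOX genes ranked higher as well, with 0 of 21 called, 0 adjusted over the list alone and list p = 0.0015. The levels came from the retinoids, with a median HOXB8 of 875 TPM in their libraries against 0 in the other toxic ones. Without both retinoids the list median was 0.04, and its adjusted p 0.00136 with the preset correlation, the only one run there, against 0.000843 with all compounds. In all, limma called 5 genes as higher and 43 as lower, of 4120 at unadjusted p under 0.05. Centring each library on its median gave 23 and 73. In this fit the variance trend of limma runs on deviations and widens the error of the strongest movers, GDF15 among them. With a trend on expression level, an alternative chosen after the results were seen, 16 and 77 genes were called, none of them a p53 target. Without the 7 toxic compounds that have no library on days 8 to 21 the calls numbered 2019, and all of the named genes lost their call once the mean length trend of a compound was a covariate, where 10 genes were higher and 3 lower.

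Over days 8 to 39 (21 against 12 compounds) the classes differed in 810 genes that were higher and 2018 that were lower in the toxic class. HK2, the hexokinase that starts glycolysis, fell with -0.82 ± 0.18 (20.8 ± 7.38 against 40.0 ± 9.67 TPM), the GABA receptor subunit GABRQ with -0.89 ± 0.22, the adhesion protein IGSF9B with -0.82 ± 0.16 and the keratin KRT7 with -0.89 ± 0.26. Rises were led by CDR1 (0.89 ± 0.24) and the histone genes HIST1H4E (0.86 ± 0.21) and HIST1H1E (0.81 ± 0.17), whose reads are hard to assign among related copies. Of 12 hypoxia and glycolysis genes 8 fell and 4 did not pass (9 fell adjusted over the list alone), with adjusted p = 0.127 with an estimated correlation. PDK1 stood at -0.71 ± 0.12 and VEGFA at -0.67 ± 0.14. Among p53 targets CDKN1A, at 0.10 ± 0.22, and GDF15, at 0.13 ± 0.28, did not pass in this window, while MDM2 did, at 0.17 ± 0.06. HOX genes again ranked higher with 0 of 21 called and 0 adjusted over the list alone (list p = 0.0166). HOXB8, at 1.36 ± 5.39, had a median of 2851 TPM in retinoid libraries of days 8 to 21 against 0.23 in the other toxic ones. Without the retinoids the list median was 0.02, with 1 rise and adjusted p 0.00666 with the preset correlation (0.00434 with all compounds), a size at which traces carried between libraries are not ruled out.

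A sign of RNA quality moved with the class on the later days. The slope of a library's deviation from the same-day non-toxic mean on transcript length had a median of -0.186 log2 per doubling in the 19 toxic libraries of day 21, against 0.00245 in the 11 non-toxic ones. On day 15 the medians were -0.0627 and -0.000348. Without days 15 and 21 the later class comparison called 100 genes, 89 of them higher and 11 lower, and with the mean length trend as a covariate 949 higher and 305 lower. In both settings the excess of lower genes turned into an excess of higher ones. It stayed when single libraries with a strong slope were left out instead. Calls were then 472 higher and 1163 lower without those below -0.15, and 240 and 334 without those below -0.1. Of CDR1, HIST1H4E, HIST1H1E, HK2, GABRQ, IGSF9B and KRT7 only HIST1H1E passed without these days (0.81 ± 0.17 with all days, 0.44 without). More of the named genes held in the other settings. Without libraries below -0.1, 3 of 10 values of the later comparison kept direction and call. With the length trend as a covariate, 7 of 20 values from the early and later comparisons did, and 13 were weaker. The genes named above for the early comparison were not among those 7.

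**Figure D2:**
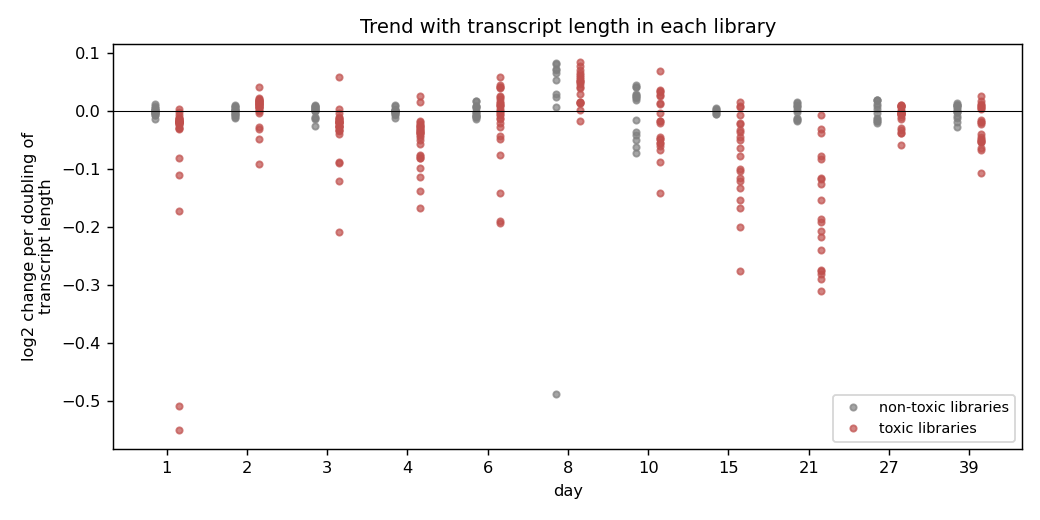
Slope of each library's deviation from the same-day non-toxic mean on log2 transcript length, by day, with non-toxic libraries in grey and toxic libraries in red. On day 21 the toxic median is -0.186 and 14 of 19 toxic libraries lie below -0.1.

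Each of 28 toxic compounds was then set against the non-toxic libraries of its days, and each of the 16 non-toxic compounds against the other ones as background. Among the non-toxic compounds limma called 0 genes for 11, while their counts at unadjusted p under 0.05 ran from 253 for glucosamine to 1331 for acetaminophen. Glyphosate gave 39 calls, naproxen 14, DMSO 12, aspirin 5 and ibuprofen 5161. The toxic compounds gave 10 (L-phenylalanine) to 13714 calls (cadmium), with a median of 3819.5, below the count of ibuprofen. Of them 25 exceeded the 39 calls of glyphosate, the second highest non-toxic count. Without libraries of a length trend below -0.15, dioxin went from 2750 to 80 calls and 2-imidazolidinethione from 79 to 1321. The latter lost none of its own libraries, whose lowest slope was -0.088. The only library its comparison lost was a control, ibuprofen on day 8, which is among the controls of the main fits. The background was not fitted again without libraries below -0.15, so the comparison with it holds for all libraries only. The median difference of genes with at least 10 TPM was within 0.1 log2 of 0 except in cadmium (-0.67), arsenic (-0.36), vincristine (-0.23), monosodium glutamate (-0.12), okadaic acid (-0.11), ibuprofen (-0.11) and ibuprofen against naproxen (-0.13). It was next largest in 5-fluorouracil (0.09), dioxin (-0.08) and Bis-I (-0.08). Changes sit on top of these shifts, and the counts after centring are printed where the share of rises moved by over 10 percentage points or rises and falls changed places.

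**Figure D3:**
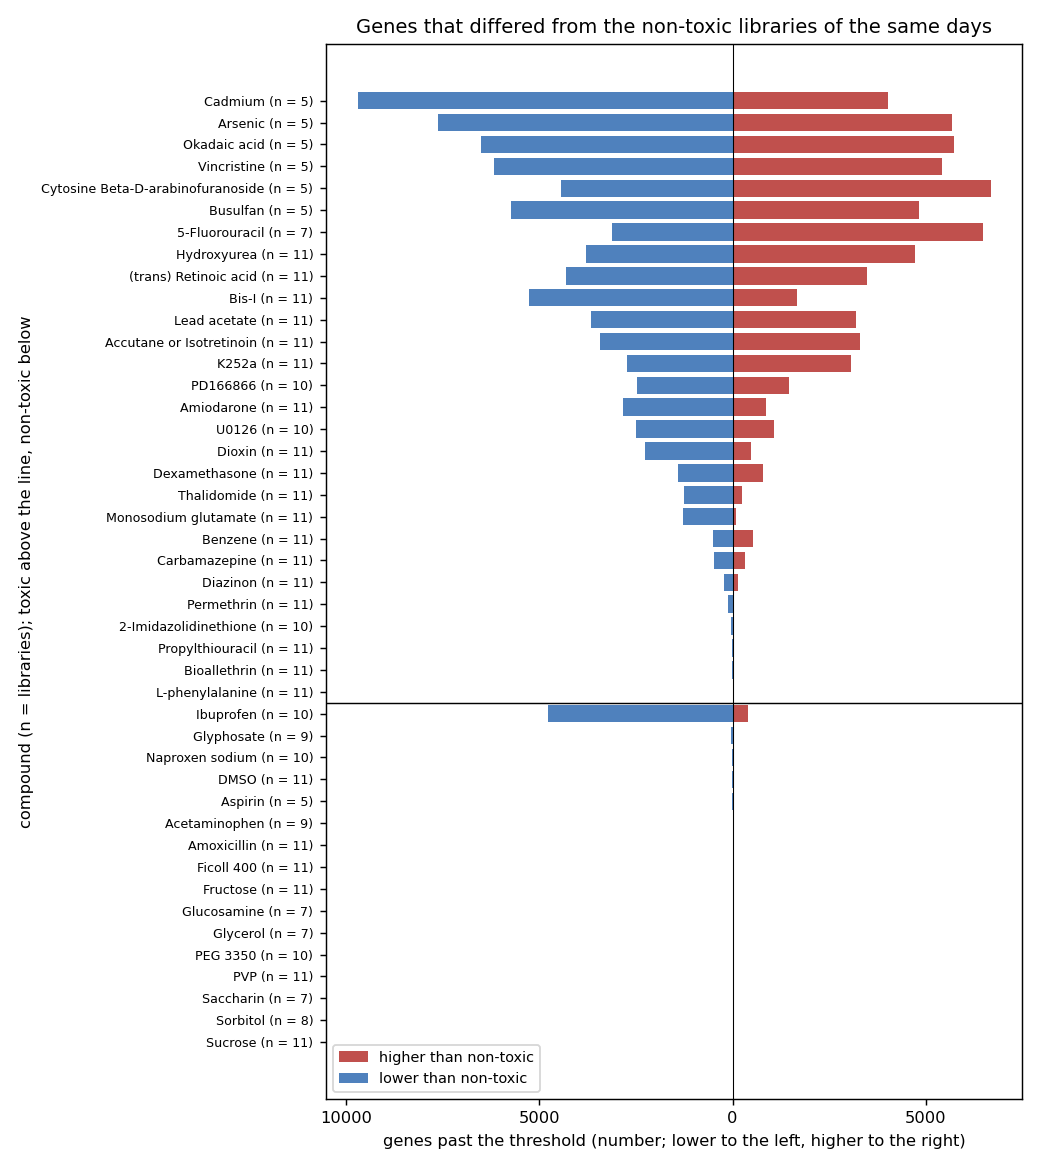
Number of genes that passed for every toxic compound and every non-toxic compound, with rises and falls as separate bars on a linear axis from 0. Cadmium has 13714 calls, L-phenylalanine 10, and 11 of the 16 non-toxic compounds have 0.

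Under all-trans retinoic acid (1.7 µM, 11 libraries) all 21 HOX genes, which set position along the body axis, rose (21 adjusted over the list alone; list p = 1.08e-168). HOXB8 was at 1928 ± 1021 against 0.0239 ± 0.0534 TPM, a difference of 10.46 ± 0.13, with HOXB5 at 9.09 ± 0.09 and HOXB9, outside the list, at 9.02 ± 0.24. These sizes depend on the added 1 TPM because the non-toxic level was near 0. Of 14 retinoic acid targets 13 rose and 1 fell (13 and 1 adjusted over the list alone; list p = 9.09e-20). The reductase DHRS3 rose by 5.25 ± 0.11 and the receptor RARB by 4.68 ± 0.09 (107 ± 20.1 against 3.20 ± 0.656 TPM), each on 11 of 11 days. The exception was CYP26C1, a retinoic acid hydroxylase, with -2.13 ± 0.10. Its relative CYP26A1 averaged 1.57 ± 0.18 over all days but lay below the non-toxic mean early, at 278 TPM against 442 ± 13.7 on day 4, and above it late, at 1020 against 26.9 ± 3.44 on day 39. SIX2 (-4.88 ± 0.16), the GABA-making enzyme GAD1 (-3.63 ± 0.12) and CA8 (-3.59 ± 0.23) fell most. Of 7 GABAergic genes 1 rose and 3 fell (1 and 3 adjusted over the list alone; list p = 0.0329). In all 3467 genes rose and 4312 fell, or 4310 and 3880 after centring.

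Isotretinoin (13-cis, 0.5 µg/ml, 11 libraries) raised 20 of 21 HOX genes (21 adjusted over the list alone; list p = 1.86e-166) and 13 of 14 retinoic acid targets, with CYP26C1 falling (13 and 1 adjusted over the list alone; list p = 2.93e-18). HOXB8 stood at 10.31 ± 0.15, DHRS3 at 4.83 ± 0.11 and RARB at 4.44 ± 0.08. SIX2 (-4.79 ± 0.18), CA8 (-3.52 ± 0.25) and ESRRB (-3.43 ± 0.17) fell most. Of 10 measured midbrain and floor plate genes 6 rose and 2 fell (6 and 3 adjusted over the list alone; list p = 0.0256), among them PAX8 at 3.37 ± 0.22 and PAX2 at 1.90 ± 0.17. In all 3292 genes rose and 3427 fell, or 3884 and 3325 after centring. CYP26A1, at 0.84 ± 0.15 over all days, also turned its direction on days 1 to 6 alone, to -0.56.

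The retinoids share 2737 rises and 2970 falls. Independent lists of these sizes would share 699 and 906, and with the 16 non-toxic compounds split into 8 and 8 separate controls the shared calls numbered 2514 and 2394. Across genes the differences correlated at r = 0.951 with split controls, genes not being independent replicates.

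Tested directly on the same 11 days, the stereoisomers differed in 87 genes higher and 86 lower under the all-trans form, at doses that come to about the same molar concentration, since isomers share 1 molar mass. Retinoic acid targets were higher under it as a list, 4 of 14 called (9 adjusted over the list alone; list p = 1.14e-05), with CYP26B1 at 0.88 ± 0.11 and CYP26A1 at 0.73 ± 0.14. HOX genes had 0 of 21 called and 0 adjusted over the list alone, but ranked higher together (median 0.16; list p = 0.000445). The largest differences were the sulfatase SULF1 (1.31 ± 0.18), the interferon-induced IFITM1 (1.21 ± 0.14) and CPT1A of fatty acid import into mitochondria (1.09 ± 0.11). POU4F1 (-0.96 ± 0.18), LMX1B (-0.83 ± 0.11) and the neuropeptide SST (-0.83 ± 0.11) were lower. Neural progenitor genes were lower too, 3 of 12 called (4 adjusted over the list alone; list p = 0.00313), FABP7 at -0.53 ± 0.05 and HES5 at -0.47 ± 0.07. Of 6 NOTCH targets 2 were lower, HES5 and HES4 (3 adjusted over the list alone; list p = 0.00153). The 95% interval of a difference had a median half-width of 0.13 log2, and lay within 1 log2 either way for 99.8% of 10328 genes. With day left out of the model the comparison called 0 genes, so the calls rest on pairing libraries by day.

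Metal compounds turned on the metallothioneins, small metal-binding proteins. Under cadmium (50 µM, 5 libraries) all 10 metallothionein and zinc export genes rose (10 adjusted over the list alone; list p = 1.67e-61). MT2A was at 29934 ± 8102 against 6.43 ± 2.61 TPM, MT1G at a difference of 13.04 ± 0.09 and MT1E at 12.52 ± 0.14, with reads partly shared among these near copies. All 12 heat shock genes rose (12 adjusted over the list alone; list p = 2.17e-11). The small heat shock protein CRYAB rose by 8.17 ± 0.28, HSPA1A by 7.61 ± 0.09 and HSPA1B, nearly the same in sequence, by 6.86 ± 0.08. Of 10 NRF2 targets 9 rose (9 adjusted over the list alone; list p = 0.00158), heme oxygenase HMOX1 by 8.50 ± 0.14 and ME1 by 4.51 ± 0.10. The remaining one, the glutathione synthesis gene GCLC, fell with -0.41 ± 0.06 but was higher by 0.26 after centring. All 8 immediate early genes rose (8 adjusted over the list alone; list p = 1.56e-08), FOS by 6.54 ± 0.19 and EGR1 by 6.41 ± 0.13. Of 13 ATF4 and amino acid response genes 12 rose and 1 fell (12 and 1 adjusted over the list alone; list p = 6.77e-05), ATF3 by 5.46 ± 0.12 and DDIT3 by 4.47 ± 0.13. Of 8 epithelial and choroid plexus genes 7 rose (7 adjusted over the list alone; list p = 0.0374), EPCAM by 2.80 ± 0.16. FAM70A (-3.53 ± 0.05), CYP26C1 (-3.49 ± 0.07) and GAS1 (-3.36 ± 0.07) fell most. In all 4021 genes rose and 9693 fell, or 9056 and 4769 after centring.

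Arsenic (5 µM, 5 libraries) raised all 10 NRF2 targets (10 adjusted over the list alone; list p = 4.56e-06), HMOX1 to 4492 ± 2169 against 5.51 ± 1.17 TPM, all 10 metallothionein and zinc export genes (10 adjusted over the list alone; list p = 7.45e-11) and all 12 heat shock genes (12 adjusted over the list alone; list p = 0.0156). The heat shock protein HSPA6, outside the list, rose by 10.99 ± 0.18 and the oxidative stress gene OSGIN1 by 5.70 ± 0.22, and MT2A stood at 3438 ± 678 against 6.43 ± 2.61 TPM. MT1A, at 0.29 ± 0.10, rested on the day 2 library and was at -0.01 without it. Progenitor and neurogenic genes fell: 10 of 12 neural progenitor genes with 2 rises (10 and 2 adjusted over the list alone; list p = 0.00683) and 12 of 13 neurogenic transcription factors with 1 rise (12 and 1 adjusted over the list alone; list p = 0.0235). The NOTCH effector HES5 went to 4.54 ± 2.85 against 254 ± 43.4 TPM, LHX5 to 2.52 ± 1.09 against 131 ± 87.3 TPM, with NEUROD4 at -4.38 ± 0.08 and MUSTN1 at -4.93 ± 0.15. Of 21 p53 targets 18 rose and 1 fell (18 and 1 adjusted over the list alone; list p = 0.0076), GDF15 by 8.24 ± 0.19. Of 13 ATF4 genes 12 rose (12 adjusted over the list alone; list p = 4.77e-05), all 8 immediate early genes rose (8 adjusted over the list alone; list p = 1.71e-06), and of 18 FGF and ERK targets 17 rose and 1 fell (17 and 1 adjusted over the list alone; list p = 0.0183), FOS by 7.46 ± 0.17. In all 5680 genes rose and 7628 fell, or 8726 and 5203 after centring.

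Lead acetate (30 µM, 11 libraries) moved several of the same groups. All 10 NRF2 targets rose (10 adjusted over the list alone; list p = 9.72e-17), the quinone reductase NQO1 by 2.72 ± 0.09 and HMOX1 by 2.41 ± 0.11, and 7 of 10 metallothionein and zinc export genes rose (7 adjusted over the list alone; list p = 7.18e-11), MT2A to 519 ± 608 against 21.0 ± 25.4 TPM. MT1A (-0.04 ± 0.07), MT1H (-0.01 ± 0.04) and MT3 (0.28 ± 0.15) did not pass. Of 21 p53 targets 20 rose (21 adjusted over the list alone; list p = 8.05e-15), all 10 ER chaperones rose (10 adjusted over the list alone; list p = 2.42e-05), XBP1 by 0.87 ± 0.07, and of 13 ATF4 genes 11 rose and 1 fell (11 and 1 adjusted over the list alone; list p = 4.77e-05). Of 12 heat shock genes 11 rose and CRYAB fell (11 and 1 adjusted over the list alone), HSPB1 by 0.62 ± 0.07, with adjusted p = 0.106 with an estimated correlation. HSPA1A, at 0.17 ± 0.07, was at -0.07 on days 1 to 6 alone. FGF19 (-1.29 ± 0.12), HGFAC (-1.18 ± 0.12) and HK2 (-1.10 ± 0.19, -0.02 on days 1 to 6 alone) fell most. In all 3202 genes rose and 3663 fell.

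Drugs that act on DNA raised every p53 target measured. All 21 rose under AraC (5 µM, 5 libraries; list p = 1.36e-21), busulfan (50 µg/ml, 5 libraries; list p = 2.65e-26), 5-fluorouracil (10 µM, 7 libraries; list p = 1.60e-12) and hydroxyurea (250 µM, 11 libraries; list p = 9.44e-10), and 21 passed adjusted over the list alone in each. CDKN1A was at 1338 ± 647 against 22.3 ± 6.64 TPM under AraC and rose by 5.34 ± 0.14 under busulfan, 3.53 ± 0.18 under 5-fluorouracil and 2.05 ± 0.11 under hydroxyurea. The stress cytokine GDF15 rose by 6.83 ± 0.22, 6.04 ± 0.22, 2.32 ± 0.22 and 1.85 ± 0.15 in the same order. PLK3 and TP53INP1 rose over all days of hydroxyurea, by 0.27 ± 0.06 and 0.25 ± 0.06, but stood at -0.20 and -0.06 on days 1 to 6 alone.

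Progenitor genes fell under AraC and busulfan. Of 12 neural progenitor genes 10 fell under each, with 1 and 2 rises (10 adjusted over the list alone in each; list p = 0.000597 and 0.00632). HES5 had -5.70 ± 0.24 and -5.03 ± 0.27, the nephrin-like adhesion gene KIRREL2 -3.80 ± 0.26 and -4.25 ± 0.25, and PRDM13, a factor of spinal and retinal interneurons, -4.08 ± 0.27 under AraC and 4.66 ± 6.78 against 54.8 ± 26.9 TPM under busulfan. FGF and ERK targets rose under both, 18 and 17 of 18 (18 and 17 adjusted over the list alone; list p = 0.00733 and 0.00289), FOSL1 by 4.68 ± 0.18 and 4.28 ± 0.16. Under AraC 5 of 6 NOTCH targets fell and 1 rose (5 and 1 adjusted over the list alone; list p = 0.000782), 13 of 14 G2 and mitosis genes fell (13 adjusted over the list alone; list p = 0.0183), PLK1 with -1.80 ± 0.05, and 11 of 13 neurogenic factors fell (11 adjusted over the list alone; list p = 0.0232). All 12 mesenchymal and matrix genes rose under busulfan (12 adjusted over the list alone; list p = 0.0374), TAGLN by 3.77 ± 0.20, and 9 of 10 NRF2 targets rose with 1 fall (9 and 1 adjusted over the list alone; list p = 0.00567). Calls numbered 6678 rises and 4443 falls for AraC and 4819 and 5725 for busulfan, where rises became the more numerous after centring (5899 and 4764), without the day 3 library (4993 and 4779) and without the libraries of a strong length trend (4920 and 4714).

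Cell cycle genes moved in opposite directions under 5-fluorouracil and hydroxyurea. All 14 S phase genes fell under 5-fluorouracil (14 adjusted over the list alone; list p = 0.00229), RRM2 with -1.84 ± 0.13, and all 14 rose under hydroxyurea (14 adjusted over the list alone; list p = 0.00229), RRM2, a subunit of the ribonucleotide reductase that hydroxyurea inhibits, by 1.45 ± 0.08. A test between these compounds was not run. G2 and mitosis genes fell under 5-fluorouracil, 14 of 14 (14 adjusted over the list alone; list p = 0.0147), AURKB with -2.14 ± 0.17 and TOP2A with -2.08 ± 0.18. Under hydroxyurea all 14 rose (14 adjusted over the list alone), with adjusted p = 0.172 with an estimated correlation. TNFRSF10C (2.91 ± 0.19) and TFPI2 (2.84 ± 0.27) rose under 5-fluorouracil and the peripherin gene PRPH fell (-2.12 ± 0.28). Of 18 FGF and ERK targets 18 rose there (18 adjusted over the list alone; list p = 0.0129), and all 16 measured cholesterol synthesis genes fell (16 adjusted over the list alone; list p = 0.0303). Under hydroxyurea neuropeptide NPY rose by 3.32 ± 0.25, IFITM1 by 3.04 ± 0.22 and ID3 by 2.40 ± 0.20, while 4 of 7 GABAergic genes fell (4 fell and 1 rose adjusted over the list alone; list p = 0.00439), SLC32A1 with -2.27 ± 0.13 and GAD1 with -1.92 ± 0.09. Calls numbered 6470 rises and 3115 falls for 5-fluorouracil (4176 and 4741 after centring) and 4717 and 3793 for hydroxyurea.

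AraC and 5-fluorouracil, both pyrimidine analogs, were compared over their 5 shared days at different doses. AraC had 2726 genes higher and 1748 lower. Of 21 p53 targets 13 were higher under AraC (18 adjusted over the list alone; list p = 2.31e-07), GDF15 by 3.98 ± 0.20, and the cytidine deaminases APOBEC3B and APOBEC3C by 4.31 ± 0.33 and 3.80 ± 0.26. The urokinase gene PLAU was higher by 4.21 ± 0.41 and the apelin receptor APLNR by 4.05 ± 0.60. HES5 (-4.68 ± 0.64) and PTF1A (-2.95 ± 0.49) were lower, with 8 of 12 neural progenitor genes (9 adjusted over the list alone; list p = 0.0362) and 5 of 6 NOTCH targets (5 adjusted over the list alone; list p = 0.000256). The median half-width of the normal 95% interval was 0.21 log2, which is too small for 5 shared days. Leaving out single days gave 644 to 4381 calls, the lowest without day 3, and APLNR and PTF1A lost their calls without day 3 and without day 4.

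**Figure D4:**
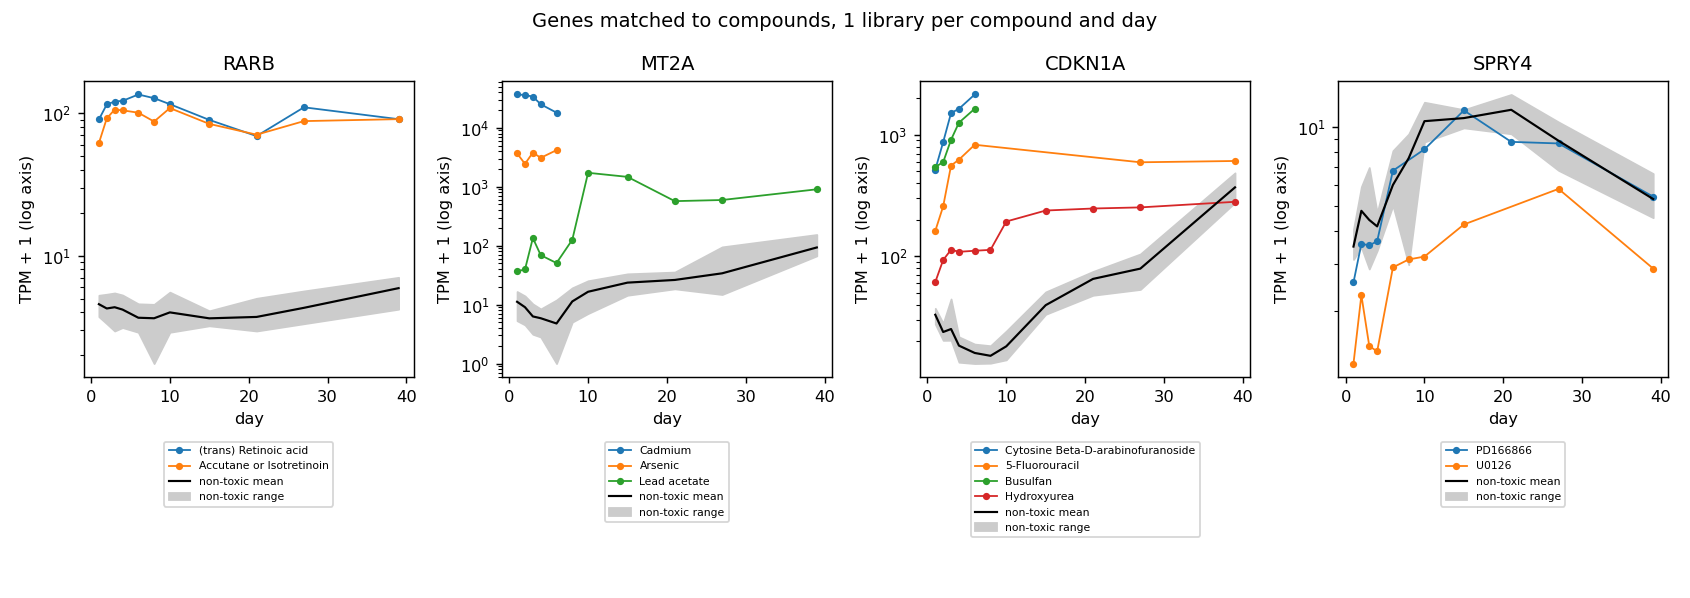
TPM plus 1 on a log axis by day for RARB under the retinoids, MT2A under the metals, CDKN1A under the drugs that act on DNA and SPRY4 under PD166866 and U0126, 1 point per library, with the mean (black) and range (grey) of the non-toxic libraries. RARB averages 107 against 3.20 TPM for retinoic acid against the non-toxic class and MT2A 29934 against 6.43 TPM for cadmium.

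Inhibitors of growth factor signalling lowered the targets of that pathway. U0126, an inhibitor of the ERK-activating kinase MEK (10 µM, 10 libraries), lowered 15 of 18 FGF and ERK targets (17 adjusted over the list alone; list p = 1.10e-05): EGR1 at -1.54 ± 0.11, the feedback inhibitor SPRY4 at -1.24 ± 0.08 (1.86 ± 1.40 against 5.59 ± 2.67 TPM), cyclin CCND1 at -1.17 ± 0.07 and ETV5 at -1.09 ± 0.08. Matrix genes fell with them, 11 of 12 mesenchymal and matrix genes (12 adjusted over the list alone; list p = 0.00633), among them decorin DCN with -1.99 ± 0.13, next to biglycan BGN (-2.33 ± 0.12) and IGFBP7 (-2.18 ± 0.14). Of 11 astrocyte genes 10 fell (10 adjusted over the list alone; list p = 0.00418), AQP4 with -1.23 ± 0.12 and GFAP with -1.17 ± 0.14. Of 16 cholesterol genes 15 fell (15 adjusted over the list alone; list p = 0.0195), of 14 retinoic acid targets 11 fell (11 adjusted over the list alone; list p = 0.00538), STRA6 with -1.05 ± 0.12, and of 8 immediate early genes 4 fell (5 adjusted over the list alone; list p = 0.0076). SIX2 rose by 1.17 ± 0.09 and the forebrain factor LHX2 by 0.85 ± 0.17. Calls numbered 1069 rises and 2496 falls.

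PD166866, an inhibitor of the FGF receptor (2.5 µM, 10 libraries), lowered 12 of the 18 targets (13 adjusted over the list alone; list p = 0.0232), CCND1 at -0.84 ± 0.07, ETV5 at -0.57 ± 0.07 and SPRY1 at -0.55 ± 0.07. ETV1 and FOS, at -0.20 ± 0.06 and -0.47 ± 0.12, were at 0.06 and 0.02 on days 1 to 6 alone, and SPRY4, at -0.18 ± 0.07, lost its call after centring. Amino acid response genes rose, 9 of 13 with 2 falls (10 and 2 adjusted over the list alone; list p = 3.95e-10), the glutathione-degrading CHAC1 by 1.37 ± 0.10, and 9 of 10 NRF2 targets rose (9 adjusted over the list alone; list p = 0.000132), the cystine transporter SLC7A11 by 1.41 ± 0.07. PCK2 of gluconeogenesis rose by 1.39 ± 0.09. Neural progenitor genes fell, 7 of 12 (9 adjusted over the list alone; list p = 0.000997), FABP7 with -0.61 ± 0.04, and 8 of 11 astrocyte genes fell (8 adjusted over the list alone; list p = 0.04), AQP4 with -0.81 ± 0.09. CYP26B1 had -1.12 ± 0.06 and COL8A1 -1.09 ± 0.16. Calls numbered 1465 rises and 2467 falls, but rises were the more numerous without the libraries of a strong length trend (1624 and 1393) and on days 1 to 6 alone (1952 and 1488). PD166866 and U0126 share 538 rises and 1378 falls where independent lists would share 96.0 and 377, and with split controls 302 and 825.

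Kinase inhibitors Bis-I and K252a had different leading genes, without a test between them. K252a (30 nM, 11 libraries) raised 12 of 13 ATF4 and amino acid response genes (12 adjusted over the list alone; list p = 1.00e-58), NUPR1 by 3.43 ± 0.16 and CHAC1 by 3.33 ± 0.11, with PCK2 at 101 ± 21.1 against 5.68 ± 4.27 TPM. SLC7A11 rose by 3.46 ± 0.08 among 9 of 10 NRF2 targets (9 adjusted over the list alone; list p = 1.56e-08), and 7 of 10 ER chaperones rose (7 rose and 1 fell adjusted over the list alone; list p = 0.0265). Of 12 mesenchymal and matrix genes 11 rose and 1 fell (11 and 1 adjusted over the list alone), a list with a median of 0.84 and adjusted p = 0.25 with an estimated correlation. Of 12 synaptic genes 11 fell (11 adjusted over the list alone) and of 14 pan-neuronal genes 11 fell (12 adjusted over the list alone), with adjusted p = 0.175 and 0.47 with an estimated correlation. GFAP (-1.79 ± 0.13), PRPH (-1.51 ± 0.19) and GABRQ (-1.36 ± 0.15) fell most. Bis-I, a protein kinase C inhibitor (4 µM, 11 libraries), lowered all 12 mesenchymal and matrix genes (12 adjusted over the list alone; list p = 0.0232), TAGLN at -1.74 ± 0.11 and DCN at -1.71 ± 0.16, with IGFBP7 at -2.51 ± 0.16 and the smooth muscle actin ACTG2 at -2.23 ± 0.17. It lowered 5 of 7 GABAergic genes (5 adjusted over the list alone; list p = 0.000435), SLC32A1 at -1.71 ± 0.12, and raised 16 of 21 p53 targets (17 adjusted over the list alone; list p = 3.62e-05), CDKN1A by 1.08 ± 0.09. PMEL (1.48 ± 0.14), RENBP (1.34 ± 0.11) and NPY (1.21 ± 0.24) rose most. Calls numbered 3056 rises and 2724 falls for K252a (2874 and 3598 after centring, 2480 and 3181 on days 1 to 6 alone) and 1667 and 5271 for Bis-I (3256 and 3935 after centring). They share 550 rises and 1518 falls (312 and 880 for independent lists, 442 and 1127 with split controls), while 172 genes rose under Bis-I and fell under K252a and 946 the reverse, where independent lists would give 278 and 987.

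Okadaic acid, an inhibitor of protein phosphatases (3 nM, 5 libraries), raised the WNT inhibitor DKK1 by 6.83 ± 0.24 and the stress factor ATF3 by 6.26 ± 0.23. Of 8 immediate early genes 7 rose (7 adjusted over the list alone; list p = 8.44e-06), of 21 p53 targets 19 rose and 1 fell (19 and 1 adjusted over the list alone; list p = 0.000413), of 18 FGF and ERK targets 17 rose and 1 fell (17 and 1 adjusted over the list alone; list p = 0.00733), and all 10 ER chaperones and all 10 NRF2 targets rose (10 and 10 adjusted over the list alone; list p = 0.00119 and 0.00271). Of 13 ATF4 genes 9 rose and 3 fell (9 and 3 adjusted over the list alone; list p = 0.0102). The homeobox genes LHX5 (-5.51 ± 0.24), UNCX (-5.37 ± 0.27) and LHX1 (-5.32 ± 0.25) fell most. Calls numbered 5722 rises and 6499 falls (6624 and 5682 after centring).

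Vincristine, which blocks microtubules (1 nM, 5 libraries), raised 16 of 21 p53 targets with 1 fall (16 and 1 adjusted over the list alone; list p = 1.75e-05), CDKN1A by 2.20 ± 0.20 and GDF15 by 2.14 ± 0.27, and all 8 immediate early genes (8 adjusted over the list alone; list p = 0.00914). FOSL1 rose by 2.36 ± 0.23, while LHX5 (-2.56 ± 0.33), TMEFF1 (-2.06 ± 0.33) and PTF1A (-1.77 ± 0.25) fell. Its matched list, G2 and mitosis, had 3 rises and 5 falls among 14 genes (2 and 5 adjusted over the list alone; list p = 0.986), with a median of 0.05 and a mean of -0.06, TOP2A at -0.76 ± 0.16 and AURKA at 0.44 ± 0.09. After centring the list had 9 rises and 2 falls. HOX genes had 19 of 21 rises (20 adjusted over the list alone; list p = 5.05e-05), HOXA4 at 0.87 ± 0.21. The day 4 library, in which 64.0% of 1642 genes listed at 0 in nearly all non-toxic libraries reached 1 TPM, weighs on all of these. The calls were 5405 rises and 6178 falls (7988 and 3747 after centring), and 5493 in total without that library, where AURKB, CENPF and UBE2C, at -0.28 ± 0.10, -0.40 ± 0.16 and -0.23 ± 0.07, turned to 0.08, 0.24 and 0.01. CCNB1 and CDC20, at 0.32 ± 0.13 and 0.26 ± 0.12, turned to -0.04 and -0.06 without the day 6 library.

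Sterol genes answered dexamethasone (100 µM, 11 libraries), a synthetic glucocorticoid. All 16 measured cholesterol synthesis genes rose (16 adjusted over the list alone; list p = 6.21e-71), MVD by 1.73 ± 0.07 and DHCR7 by 1.57 ± 0.05. The sterol exporters ABCG1 (-1.84 ± 0.09) and ABCA1 (-1.37 ± 0.11) fell on 11 of 11 days. PLA2G3 rose by 2.11 ± 0.09 and apolipoprotein APOD by 2.06 ± 0.14. Of 10 glucocorticoid targets 2 rose, FKBP5 by 0.84 ± 0.12 and TSC22D3 by 0.35 ± 0.04 (2 adjusted over the list alone), with adjusted p = 0.227 with an estimated correlation, and FKBP5 lost its call on days 1 to 6 alone (0.11). Of 10 NRF2 targets 8 rose (9 adjusted over the list alone; list p = 0.00188). Calls numbered 782 rises and 1417 falls. Amiodarone (1 µg/ml, 11 libraries) raised 12 of the 16 cholesterol genes (12 adjusted over the list alone; list p = 1.14e-05), MVD by 0.50 ± 0.06. The stromal protein ISLR rose by 0.99 ± 0.12, and COL24A1 (-0.79 ± 0.11) and the dopamine-making enzyme TH (-0.85 ± 0.11, -0.14 on days 1 to 6 alone) fell. Of 12 mesenchymal and matrix genes 7 rose (9 adjusted over the list alone), with adjusted p = 0.0592 with an estimated correlation. Calls numbered 863 rises and 2844 falls for amiodarone (1455 and 2350 after centring, 724 and 1625 on days 1 to 6 alone, 537 and 999 without the libraries of a strong length trend).

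2-Imidazolidinethione (0.4 mM, 10 libraries) raised the same sterol group, 5 of 16 called (14 adjusted over the list alone; list p = 7.16e-06), with the acetyl-CoA transferase ACAT2 at 0.22 ± 0.03 and the sterol-regulated TMEM97 at 0.30 ± 0.05, outside the list, while ABCG1 fell (-0.46 ± 0.08). GADD45B rose by 0.47 ± 0.12 and COL7A1 fell (-0.46 ± 0.10). Of 10 ER chaperones 1 rose (6 adjusted over the list alone; list p = 0.0268). Calls numbered 29 rises and 50 falls, but 53 and 86 after centring, 154 and 792 on days 1 to 6 alone, and 147 and 1174 without the libraries of a strong length trend. None of those was a library of 2-imidazolidinethione itself. Propylthiouracil (25 µg/ml, 11 libraries) had 10 rises and 18 falls (19 and 125 after centring, 117 and 246 on days 1 to 6 alone, 59 and 376 without the libraries of a strong length trend). FAM46A rose by 0.22 ± 0.05 and the mitochondrial glycine cleavage gene GCSH by 0.13 ± 0.03, and the histone gene HIST2H2AC (-1.07 ± 0.26) and the keratins KRT17 (-0.68 ± 0.17) and KRT7 (-0.65 ± 0.16) fell. On days 1 to 6 alone FAM46A, GCSH and both keratins lost their calls. Set against each other on 10 shared days, these cyclic thioureas at different doses differed in 0 genes by limma, with 1305 at unadjusted p under 0.05. The median half-width of the interval was 0.12 log2. As a list, cholesterol synthesis ranked lower under propylthiouracil (0 of 16 called, 9 adjusted over the list alone; list p = 0.00155), and ABCG1, chosen after its values were seen, had a difference of 0.62 with an interval from 0.47 to 0.76.

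Dioxin (3 nM, 11 libraries) raised 3 of 7 AHR targets, the receptor it binds (4 adjusted over the list alone; list p = 0.000768): CYP1B1 by 0.55 ± 0.11, the repressor AHRR by 0.53 ± 0.11 and NQO1 by 0.21 ± 0.07. CYP1B1 was at 55.1 TPM on day 27 against 16.5 ± 6.92 in 12 non-toxic libraries. The standard marker CYP1A1 had 0.03 ± 0.08 (1.04 ± 1.11 against 1.04 ± 1.09 TPM) and did not pass. TEX101 (0.94 ± 0.21), IFITM1 (0.84 ± 0.19) and the class II antigen gene HLA-DRA (0.81 ± 0.17) rose most, and B3GAT2 (-0.76 ± 0.14), IGF2 (-0.63 ± 0.11) and C1orf187 (-0.61 ± 0.15) fell most. Calls numbered 482 rises and 2268 falls (980 and 1582 after centring, 72 and 270 on days 1 to 6 alone), but 42 and 38 without the libraries of a strong length trend, where TEX101, IFITM1, B3GAT2 and NQO1 did not pass.

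Among the insecticides diazinon (10 µM, 11 libraries) raised ABCG1 by 0.75 ± 0.07 on 11 of 11 days, together with CDR1 (1.08 ± 0.20) and KIAA0408 (1.46 ± 0.29, reads of an overlapping gene being possible). RGS5, a regulator of G protein signalling, fell with -0.65 ± 0.11 and PPP1R14A with -0.72 ± 0.19. CDR1 was also among the largest rises of amiodarone, benzene, carbamazepine and both class comparisons, and RGS5 among the largest falls of benzene and bioallethrin. Neither is therefore particular to diazinon, and a batch that followed class could not be told apart from such shared changes. Of 6 NOTCH targets 2 fell, HES4 with -0.38 ± 0.09 and NRARP with -0.23 ± 0.04 (2 adjusted over the list alone; list p = 0.00567). Calls numbered 146 rises and 229 falls (169 and 445 after centring, 352 and 922 on days 1 to 6 alone, 278 and 620 without the libraries of a strong length trend), and of the named genes ABCG1 alone among the largest changes kept its call on days 1 to 6. Permethrin (2.5 µM, 11 libraries) had 49 rises and 117 falls (96 and 308 after centring, 104 and 935 on days 1 to 6 alone, 88 and 641 without the libraries of a strong length trend), with PALM3 at 0.32 ± 0.07, IGSF9B at -0.64 ± 0.14 and the synapsin SYN3 at -0.58 ± 0.15. Bioallethrin (10 nM, 11 libraries) had 14 and 13 (16 and 42 after centring, 204 and 678 on days 1 to 6 alone, 796 falls of 922 calls without the libraries of a strong length trend), with PUS3 at 0.28 ± 0.07, RGS5 at -0.56 ± 0.10 and the potassium channel KCNA3 at -0.44 ± 0.10. SYN3, PALM3 and RGS5 in bioallethrin lost their calls on days 1 to 6 alone. Compared directly on 11 shared days and at different doses, these pyrethroids differed in 0 genes by limma (692 at unadjusted p under 0.05). The median half-width of the interval was 0.12 log2, and 99.9% of 10328 genes had an interval within 1 log2 either way.

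Carbamazepine (10 µg/ml, 11 libraries) raised division genes slightly: 9 of 14 G2 and mitosis genes (14 adjusted over the list alone; list p = 0.0265), CDK1 by 0.28 ± 0.06, and 6 of 14 S phase genes (9 adjusted over the list alone; list p = 0.0342), RRM2 by 0.24 ± 0.05. NPY (0.78 ± 0.25) and AKAP14 (0.58 ± 0.16) rose, KRT7 (-0.77 ± 0.17), cardiac troponin TNNT2 (-0.62 ± 0.15) and SPON2 (-0.58 ± 0.09) fell, and of these AKAP14 alone passed on days 1 to 6. Calls numbered 320 and 479 (489 and 797 after centring, 633 and 1439 without the libraries of a strong length trend). Thalidomide (100 ng/ml, 11 libraries) gave 249 rises and 1248 falls (540 and 1235 after centring), the sorting nexin SNX15 with 0.35 ± 0.04 and SYN3 with -0.73 ± 0.15, the latter without a call on days 1 to 6. Monosodium glutamate (150 µM, 11 libraries) gave 95 and 1273 (593 and 391 after centring), but 21 and 4 without the libraries of a strong length trend and 578 and 8370 on days 1 to 6 alone. MT2A (0.67 ± 0.19) and the synuclein SNCG (0.37 ± 0.10) rose and CXXC5 (-0.49 ± 0.13) fell, none of which passed without those libraries. Its metallothionein list, 1 of 10 called (1 adjusted over the list alone; list p = 0.0076), did not pass without them or after centring either. Benzene (50 µg/ml, 11 libraries) gave 518 and 515 (783 and 1612 after centring, 203 and 515 on days 1 to 6 alone, 274 and 386 without the libraries of a strong length trend), with CDR1 at 0.89 ± 0.17, RGS5 at -0.69 ± 0.11 and thrombomodulin THBD at -0.58 ± 0.14, none past the threshold on days 1 to 6 alone. L-phenylalanine (1 mM, 11 libraries) gave 10 rises and 0 falls (12 and 11 after centring, 44 and 102 on days 1 to 6 alone, 3 and 1 without the libraries of a strong length trend), with PSMC1 of the proteasome at 0.12 ± 0.02 and PAF1, which lost its call on days 1 to 6, at 0.13 ± 0.03.

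HOX genes passed as a list in amiodarone, dioxin, diazinon, carbamazepine, thalidomide, monosodium glutamate, permethrin, propylthiouracil and 2-imidazolidinethione as well, with 3, 1, 1, 6, 1, 1, 0, 2 and 0 of 21 genes called (3, 1, 1, 8, 1, 1, 0, 2 and 0 adjusted over the list alone). The list p ran from 2.66e-08 in carbamazepine to 0.0468 in permethrin, and HOXB8 in carbamazepine had 0.89 ± 0.13. The list test ranks members against all other genes, so a list near 0 can rank higher where other genes shift down. In dioxin the HOX median was 0.0004, beside a median of -0.08 for genes with at least 10 TPM. In carbamazepine the latter median was 0.0002. In diazinon, dioxin and monosodium glutamate the call ended without the libraries of a strong length trend. Carry-over from retinoid wells and exchange of library indices were not tested, and such traces are not separated from a response to these compounds.

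In the non-toxic class the genes below were chosen after their values were seen. Ibuprofen (20 µg/ml, 10 libraries) raised CPT1A, the gate of fatty acid oxidation, by 1.87 ± 0.13 (9.69 ± 4.35 against 1.90 ± 1.06 TPM), and the lipase inhibitor ANGPTL4 by 1.73 ± 0.15, each on 10 of 10 days. Naproxen (30 µg/ml, 10 libraries) raised CPT1A by 1.11 ± 0.18, the growth factor MDK by 0.38 ± 0.04 and the polyamine enzyme ODC1 by 0.34 ± 0.05, on 10 of 10 days. Calls under ibuprofen numbered 388 rises and 4773 falls. Without its day 8 library, whose length trend was -0.488, they numbered 17 and 64, and 70 of these 81 had been called with it. Set against each other on 9 shared days, these arylpropionic acids differed in 0 genes by limma (681 at unadjusted p under 0.05), with a median half-width of 0.27 log2. CPT1A differed by 0.72 (interval 0.40 to 1.05) and ANGPTL4 by 1.17 (0.76 to 1.57), neither past the threshold. HOX genes ranked higher under ibuprofen with 0 of 21 called and 0 adjusted over the list alone (list p = 0.00313), a call that ended without that library. Cultures with DMSO had GFAP lower at -0.47 ± 0.08 and ACTG2 at -0.55 ± 0.12, among 12 falls and 0 rises. Glyphosate had 5 rises and 34 falls, ZNF771 at -0.38 ± 0.07 and INSM1 at -0.21 ± 0.04. Aspirin had 3 rises and 2 falls, HK2 at 0.35 ± 0.07 and IGFBP3 at -0.51 ± 0.11.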

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

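The tests of the ibuprofen genes without day 8 and of the vincristine response were chosen only after results were seen, as were the length trend and its limits.

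Toxic libraries of days 15 and 21 carried a trend of expression with transcript length, and 36 toxic libraries against 1 non-toxic library had a slope below -0.1. The class comparison of days 8 to 39 had 2828 calls with all days and 100 without days 15 and 21, which is in line with a contribution of RNA quality on those days. Fewer libraries per compound also lower the count, and a toxic effect that peaks on those days would look the same. The toxic and non-toxic libraries of a day carry separate name series, and no plate or batch is given. A batch that followed class could not be told apart from class, nor be measured by comparing non-toxic compounds with each other. Composition of the TPM is the less likely source, because 3068 genes were called after centring, 2556 of the 2828 among them. RNA degradation that follows from dying cells would be a biological route to the same trend, and the data hold no measure of it.

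Ibuprofen had 5161 calls, far above any other non-toxic compound. Without its day 8 library, whose length trend was -0.488, 81 genes were called, 70 of them shared with the 5161, in line with RNA quality of 1 well as the source of most. CPT1A and ANGPTL4, both targets of fatty acid receptors, kept differences of 2.00 ± 0.13 and 1.69 ± 0.15 without that library, the higher adjusted p being 4.37e-16. A response to ibuprofen in these genes is therefore left, seen on each of its 10 days.

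Vincristine on day 4 correlated with the same-day non-toxic mean at r = 0.401, against 0.993 on day 3 and 0.9498 on day 6, and its Dixon ratio was 0.923. Of 1642 genes listed at 0 in nearly all non-toxic libraries, 64.0% had at least 1 TPM in it, against at most 0.305% in the other vincristine libraries and at most 0.183% in any non-toxic one. Reads spread over silent genes, from DNA or another unspecific source, would give this picture. A response to vincristine on day 4 alone would lower the correlation as well, so that explanation cannot be told apart by it and stays open.

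PD166866 on day 21 stood apart from its other days in the length trend, with a Dixon ratio of 0.484. Its slope of -0.186 was the median of the 19 toxic libraries of that day, so it was typical of them. Toxic compounds sampled on every day had no Dixon test. U0126 on day 39 stood apart in its correlation with the non-toxic mean, with a ratio of 0.600. These and vincristine were the 3 of 32 sets beyond the limit, where chance alone gives about 1 in 20. Maneb (60 µM) had only a day 1 library and entered no comparison, and its mean scores there were 0.53 for NRF2 targets, 0.26 for heat shock and 1.77 for metallothioneins and zinc export. The highest scores of the 16 non-toxic libraries of that day were 0.08, 0.07 and 0.17. In it HMOX1 stood at 124 TPM against at most 6.08 in those libraries, MT2A at 177 against at most 15.7, and HSPA6 at 112 against at most 0.46.

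Random regroupings were used to ask whether chance can be excluded, counting how many groupings, the real one included, gave at least as many calls. For a single compound each grouping drew 1 library per day from its own libraries and its controls. The highest other count can therefore include libraries of the compound itself. Chance can be excluded at 1 of 100 for day 10 against day 1 (12394 calls, highest other 10121), day 39 against day 10 (12811, 9733), and the class on days 1 to 6 (48, 0) and on days 8 to 39 (2828, 298). Retinoic acid against isotretinoin (173, 10) and AraC against 5-fluorouracil (4474, 3127) also stood at 1 of 100. Their labels were drawn over all libraries of both compounds, not swapped within days as the fits pair them. Chance is thus not excluded for these paired comparisons. The 5 shared days of AraC and 5-fluorouracil allow too few such swaps to reach 1 of 100. For single compounds, each taken alone, chance can be excluded at 1 of 40 for retinoic acid (7779 calls, highest other 3857), 5-fluorouracil (9585, 3), isotretinoin (6719, 4098), arsenic (13308, 7071), Bis-I (6938, 6335), busulfan (10544, 658), cadmium (13714, 9174), AraC (11121, 3426), hydroxyurea (8510, 5300), K252a (5780, 5585), lead (6865, 5761), okadaic acid (12221, 9069) and PD166866 (3932, 388). That share is the lowest that 40 groupings allow, and it was not adjusted over the 28 toxic and 16 non-toxic compounds. Glyphosate (39, 5) was the only non-toxic compound to reach it. Among 16 compounds 1 can do so by chance, so chance is not excluded for glyphosate. Vincristine stood at 1 of 40 too (11583, 11282), but 5493 calls were left without its day 4 library, so its count depends on that library. The other groupings could draw the same library and were not repeated without it. Chance is therefore not excluded for vincristine.

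Chance cannot be excluded in this way for the other 14 toxic compounds. The groupings with at least as many calls numbered 6 of 40 for 2-imidazolidinethione (79 calls, highest other 6665), 4 for amiodarone (3707, 7692), 3 for benzene (1033, 3147), 3 for bioallethrin (27, 6490), 5 for carbamazepine (799, 6198), 6 for dexamethasone (2199, 7294), 6 for diazinon (375, 6265) and 2 for dioxin (2750, 3785). They numbered 4 for L-phenylalanine (10, 7836), 2 for monosodium glutamate (1368, 5878), 5 for permethrin (166, 7089), 7 for propylthiouracil (28, 6357), 4 for thalidomide (1497, 8416) and 3 for U0126 (3565, 6971). In 13 of these 14 the larger counts arose only in groupings that drew the ibuprofen library of day 8, which points to a structure of the samples. Without it the highest other count was 2 for U0126 and 15 for dexamethasone. PD166866 and glyphosate have no day 8 library, and 0 of their groupings drew that of ibuprofen. The 2 verdicts therefore do not rank the compounds by how firm their calls are.

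Among the non-toxic compounds other than glyphosate, chance cannot be excluded for aspirin (2 of 40, with 5 calls and a highest other of 7), DMSO (4, with 12 and 6728), ibuprofen (4, with 5161 and 6979) or naproxen (9, with 14 and 6710). With 0 real calls every grouping counts by construction, which says nothing on chance: all 40 for acetaminophen (highest other 3), amoxicillin (6334), Ficoll (6248), fructose (5630), glucosamine (8026), glycerol (5), PEG (6117), PVP (7036), saccharin (2), sorbitol (2) and sucrose (7362). The same holds for all 100 of permethrin against bioallethrin (highest other 3), propylthiouracil against 2-imidazolidinethione (2) and ibuprofen against naproxen (10739). The counts of 5630 to 8026 among these non-toxic compounds arose in groupings that drew the ibuprofen library of day 8 and point to a structure of the samples, while groupings without it gave at most 5. The 10739 calls in a grouping of ibuprofen and naproxen point to a structure too.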

How the results depend on the processing

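The limits on the length trend, the exclusion of days 15 and 21 and of the retinoids, the covariate, the trend on expression level and the exclusion of the ibuprofen library were tests chosen only after results were seen. The compound fits take their spread from up to 148 non-toxic libraries, so that 1 aberrant library can give as many calls as ibuprofen had, and the depth behind each TPM is unknown. Of 37 counts of calls, those within 1.5 times of the main value numbered 36 with a pseudocount of 0.5 TPM, 34 without the filter, 27 after centring and 24 without the 23 libraries with a length trend below -0.15. Of 489 values of named genes 482, 482, 473 and 459 kept direction and call in the same order. On days 1 to 6 only, 13 of 22 counts and 206 of 268 gene values held, and with 1 library left out 30 of 35 and 726 of 755. Taking the median over days moved neither class count, and a fixed block for compound neither time count.

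Where a count moved, the cause was not tested. At the limit of -0.15, however, 2-imidazolidinethione lost 1 control and none of its own libraries. That control was ibuprofen on day 8, so the rise of this compound to 1321 calls came with that removal. With a pseudocount of 0.5 TPM L-phenylalanine had 6 calls. Without the filter the class on days 1 to 6 had 74, bioallethrin 46 and retinoic acid against isotretinoin 115. After centring the class on days 1 to 6 had 96, 2-imidazolidinethione 139, benzene 2395, bioallethrin 58, carbamazepine 1286, diazinon 614, L-phenylalanine 23, permethrin 404, propylthiouracil 144 and propylthiouracil against 2-imidazolidinethione 10, and GCLC in cadmium turned to 0.26. On days 1 to 6 only, 2-imidazolidinethione had 946, amiodarone 2349, bioallethrin 882, diazinon 1274, dioxin 342, L-phenylalanine 146, monosodium glutamate 8948, permethrin 1039 and propylthiouracil 363. There CYP26A1 turned to -0.28 in retinoic acid and -0.56 in isotretinoin, PLK3 to -0.20 and TP53INP1 to -0.0608 in hydroxyurea, HSPA1A to -0.0740 in lead, and ETV1 to 0.0625 and FOS to 0.0201 in PD166866.

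Without the libraries below -0.15 the class on days 8 to 39 had 1635 calls, 2-imidazolidinethione 1321, amiodarone 1536, benzene 660, bioallethrin 922, carbamazepine 2072, diazinon 898, dioxin 80, L-phenylalanine 4, monosodium glutamate 25, permethrin 729, propylthiouracil 435 and ibuprofen against naproxen 1. With the preset correlation HOX lists then had adjusted p of 0.131 in diazinon, 0.0576 in dioxin, 0.199 in monosodium glutamate and 0.261 in ibuprofen against naproxen, and metallothioneins 0.537 in monosodium glutamate. After centring the latter had 0.132 and glucocorticoid targets in dexamethasone 0.0689. Without the filter G2 and mitosis in vincristine, not called, turned direction (0.863). For the class on days 8 to 39 calls numbered 574 without the 37 libraries below -0.1, 100 without days 15 and 21, and 1254 with the trend as a covariate, against 13 with it on days 1 to 6. Without the 7 compounds that lack days 8 to 21 the class on days 1 to 6 had 2019, with the variance trend on expression level 93 (2877 on days 8 to 39, as many within 1.5 times), and ibuprofen without its day 8 library 81. With 1 library left out vincristine ranged from 5493 to 12307 and AraC against 5-fluorouracil from 644 to 4381 (1715, 927 and 2912 between). MT1A in arsenic ranged from -0.0147 to 0.376, and in vincristine AURKB from -0.426 to 0.0796, CENPF from -0.603 to 0.244, UBE2C from -0.315 to 0.0141, CCNB1 from -0.0387 to 0.783 and CDC20 from -0.0582 to 0.676. With day left out as the pairing block, retinoic acid against isotretinoin had 0 calls, and the other 4 pairs stayed within 1.5 times.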

Other observations

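The per-day courses and the tests of early against late days described here were tests chosen only after results were seen. Proliferation, neuronal and glial genes of the non-toxic cultures changed on different schedules. MKI67 fell from 180 TPM on day 1 to 30.4 on day 10 and 7.54 on day 39. STMN2 went from 310 to 1709 and 1540, and DCX from 120 to 436 and 327. GAD2 was at 1.60, 99.2 and 72.7 TPM. GFAP was at 0.721, 43.9 and 3530 TPM on those days and had reached 235 on day 15, while AQP4 was lower on day 10 than on day 1, at 1.58 against 9.23 TPM.

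HOXB8 and HOXB9 were seen at low levels in toxic libraries other than the retinoids, most often on days 8 to 21. HOXB8 was then above 0 in 53 of 73 with a median of 0.23 TPM and a highest value of 15.7, and HOXB9 in 58 of 73 with 0.24 and 7.38. In non-toxic libraries of those days they were above 0 in 4 and 6 of 43 with medians of 0, and the retinoid medians were 2851 and 1820 TPM. On days 1 to 6 HOXB8 was above 0 in 28 of 131 other toxic libraries, the highest at 68.9 TPM, and in 0 of 79 non-toxic ones, and on days 27 to 39 in 19 of 40 and 3 of 26. Carry-over from retinoid wells and exchange of library indices were not tested, as neither plate layout nor barcodes are given, and the traces are not taken as a response. CYP1B1 under dioxin was at 22.6 TPM on day 1 against a non-toxic 14.3 and at 51.5 on day 39 against 18.8 ± 4.98.

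Whether a matched list moved more on late than on early days was asked in 11 tests on 9 compounds with an exact permutation of days. None passed after adjustment, and the lowest adjusted p was 0.137, which retinoic acid targets under retinoic acid shared with 3 other lists (mean score 1.93 on 5 early days and 2.22 on 6 late days).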
